A study of Mus musculus with 12 samples.

How the data were processed

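Gene expression was measured on Affymetrix mouse arrays in 12 samples of CD4+ CD25+ spleen T cells, 3 in each of 4 groups. Treg cells, the suppressive T cells marked by high CD25, were sorted directly from spleen. Effector T cells were sorted after 48 hours of spleen culture with anti-CD3, an antibody that triggers the T cell receptor. Each population came from C57BL/6 mice and from mice deficient in the IL-2 receptor beta chain that carry a transgene, which the labels describe as wild-type receptor beta for the thymus. Per the labels, each effector array held 1 mouse and each Treg array a pool of 3 to 15 mice, and the labels call the 3 samples of a group distinct biological replicates. Ages ran from 9 to 15 weeks for effector samples and from 7 to 33 weeks for Treg samples, and the oldest pool was transgenic Treg sample 1. Replicate numbers follow the sample titles. The description fields of C57BL/6 effector sample 3 and transgenic effector sample 2 both carry the number 1 instead, so the effector numbers are uncertain.

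The deposited values are on the log2 scale, with 1 value per probe set and array, and per the submitters' processing notes they were made with GCRMA, a background correction, normalization and summary of Affymetrix probes. The version is not given in the sources used here. RNA was amplified by 1 round of in vitro transcription, per the labels' protocols. Whether the authors normalized both populations together is not given in the sources used here. Minimum deposited log2 values were 0.296 to 0.325 on the 6 effector arrays and 0.942 to 0.957 on the 6 Treg arrays, and the 99th percentiles were 13.5 to 13.6 and 12.9 to 13.0. Levels set across the populations may therefore carry a scale difference. Array medians over all probe sets were 3.08 to 3.27.

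The table held 45101 probe sets. The 64 control probe sets were left out of the tests, and 18271 of the other 45037 were tested because they reached a log2 value of 5 on at least 3 arrays. The number of arrays limits the precision, and with 3 arrays against 3 an exact permutation test cannot give a two-sided p below 0.1.

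The tests were written for genes before the data were examined. The table and the gene table used here do not pair probe sets with genes, so probe sets were tested instead, several of which can measure 1 gene. For the same reason the disrupted receptor gene could not be looked up on the arrays, and the 17 gene lists that had been fixed in advance were not tested. Probe set identifiers were used as deposited. The control probe sets carry names of mouse genes (beta-actin, Gapdh, transferrin receptor and pyruvate carboxylase, 13 probe sets), and these were tested as a separate list.

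One linear model with 4 group means was fitted to all 12 arrays in limma 3.58.1 (R 4.3.3), with moderated variances that follow the mean level (eBayes with trend). Contrasts were transgenic minus C57BL/6 in each population, Treg minus effector in C57BL/6 mice, and the difference between both strain contrasts. Probe sets with a Benjamini-Hochberg adjusted p under 0.05 are called changed. Probe sets are named by a rule set before the data were examined and shortened to the 2 largest rises and 2 largest falls per contrast, among called probe sets whose 3 arrays of one group all lay above the 3 of the other. For the difference of strain contrasts the rule asks only for the call. Probe sets at least 4-fold apart between Treg and effector cells of C57BL/6 mice formed Treg-high and Treg-low sets, and their strain changes were set beside 100 simulations of unchanged strains. The simulated noise was independent for each probe set and array, so deviations that an array shares across a set were left out.

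The model was tested on simulated data with 200 changed probe sets among 18271. In the Treg contrast it recovered 48% of 2-fold and 91% of 4-fold changes, with 6 false calls among 145. In the effector contrast it recovered 38% of 2-fold and 92% of 4-fold changes, with 11 false calls among 141.

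Whether replicate numbers pair the arrays was checked from the deviations of each array from its group mean, correlated across probe sets. Same-numbered C57BL/6 and transgenic Treg arrays correlated at 0.58, 0.10 and 0.51, all above the minimum of 0.1, so the Treg arrays were taken as paired. Transgenic array 2 correlated slightly more with C57BL/6 array 3 (0.11) than with its own number. The pairing comes from the data and not from the labels. Same-numbered effector arrays were not paired by this check.

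Alternatives were other normalizations, filters, variance models and thresholds, array weights, fits to the arrays of a contrast alone, blocks for replicate number and for the provider's run (read from consecutive sample codes), and leaving out each array. All 6 effector arrays shared 1 run, and 4 Treg arrays, 2 per strain, shared another. Figures were drawn with matplotlib 3.10.9.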

Results

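The data set holds log2 GCRMA values of spleen Treg cells and anti-CD3-activated effector T cells from C57BL/6 mice and from transgenic mice whose peripheral T cells have a defective IL-2 receptor, with 3 arrays per group. The design asks which transcripts depend on IL-2, a growth and survival factor of T cells, in each population, and how they relate to transcripts typical of Treg cells. Arrays of one group correlated at 0.923 to 0.992 across the tested probe sets, and arrays of different populations at 0.672 to 0.778. Arrays of different strains correlated at 0.929 to 0.978 in Treg cells, about as high as the C57BL/6 Treg arrays among themselves (0.923 to 0.977). The transgenic Treg arrays correlated more closely among themselves (0.978 to 0.985). In effector cells arrays of different strains correlated at 0.953 to 0.983, against 0.985 to 0.992 within C57BL/6 and 0.965 to 0.991 within transgenic mice. Between 15223 and 15370 probe sets per effector array, and between 16558 and 16971 per Treg array, reached a log2 value of 5. In 9 probe sets the arrays fell into 2 states at least 2.00 apart on the log2 scale. State 1 held 5 of the 6 transgenic arrays (all but effector array 1) and 1 of the 6 C57BL/6 arrays (Treg array 3), so this split was associated with strain in both populations.

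In Treg cells, 147 probe sets fell and 71 rose in transgenic against C57BL/6 mice, so 67.4% of the 218 changes were falls. This excess of falls was absent with array weights (649 higher, 583 lower) and with the spike reading of the Treg arrays as a covariate (281 higher, 284 lower). The weighted C57BL/6 Treg mean rests mostly on array 2 (weight 5.02, against 0.45 for array 1 and 0.24 for array 3). With 1 array left out the rises ranged from 36 (transgenic Treg array 1) to 99 (C57BL/6 Treg array 3). The median size of a called change was 2.83-fold, and 189 were at least 2-fold. Probe set 1448759_AT fell from 11.95 ± 0.09 to 7.13 ± 0.81 (log2, mean ± SD, n = 3), a log2 change of -4.82 with a standard error of 0.39 (limma adjusted p = 0.000109). Probe set 1420788_AT fell from 9.75 ± 0.33 to 4.95 ± 1.12 (limma adjusted p = 0.000185). Probe set 1433942_AT rose from 5.93 ± 0.88 to 11.04 ± 0.29, a log2 change of 5.10 with a standard error of 0.65 (limma adjusted p = 0.00217). Probe set 1435559_AT rose from 3.69 ± 0.04, below the level used for filtering, to 8.15 ± 0.15 (limma adjusted p = 3.62e-08). In 44 of the 147 falls all 3 transgenic arrays lay below a log2 value of 5, and in 18 of the 71 rises all 3 C57BL/6 arrays did, so these folds depend on the background correction. The groups did not overlap in any of the 218 called probe sets, nor in 14.8% of all tested probe sets, against 10% by chance.

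The Treg count rose to 1232 with array weights, 565 with the spike covariate and 486 with an intensity ratio of at least 2 and no test. It fell when array 2 of C57BL/6 mice (135) or array 1 of transgenic mice (141) was left out, with the 6 Treg arrays alone (74), with a filter at log2 7 (135), and with the state of the arrays as a covariate (97). It was 354 with the replicate number as a block in the paired Treg arrays. The pairs were inferred from these same arrays, so part of this rise may come from that choice. The count was 185, of which 131 were among the 218, with the provider's run as a block. In that fit only the 4 arrays of the shared run inform the strain difference.

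In activated effector T cells, 350 probe sets rose and 197 fell in transgenic against C57BL/6 mice, and 394 of these 547 changes were at least 2-fold. Probe set 1448759_AT, which fell in Treg cells too, went from 12.79 ± 0.27 to 3.74 ± 0.66 (log2, mean ± SD, n = 3), a log2 change of -9.06 with a standard error of 0.39 (limma adjusted p = 8.85e-07). All 3 of its transgenic arrays lay below a log2 value of 5, so the size of this fall depends on the background correction. Probe set 1443937_AT fell from 13.30 ± 0.11 to 6.16 ± 0.61 (limma adjusted p = 2.41e-06). Probe set 1450357_A_AT rose from 4.57 ± 0.40 to 9.75 ± 0.18, a log2 change of 5.18 with a standard error of 0.23 (limma adjusted p = 8.85e-07). Probe set 1425519_A_AT rose from 6.35 ± 0.39 to 10.57 ± 0.15 (limma adjusted p = 5.48e-05). Of the 197 falls, 33 ended below a log2 value of 5 on all 3 transgenic arrays, and 35 of the 350 rises began below it on all 3 C57BL/6 arrays. The groups did not overlap in any of the 547 called probe sets, nor in 22.8% of all tested probe sets, against 10% by chance.

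The effector count rose to 3033 with array weights and 908 with an intensity ratio of at least 2 and no test. It fell when C57BL/6 array 1 (295), C57BL/6 array 2 (266) or transgenic array 2 (355) was left out, with the 6 effector arrays alone (223), without a filter (347), and with the state of the arrays as a covariate (220). It was 488, of which 379 were among the 547, without transgenic array 3. The purification label of that array describes fresh spleen cells while its title and source name describe cultured effector cells.

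**Figure D1:**
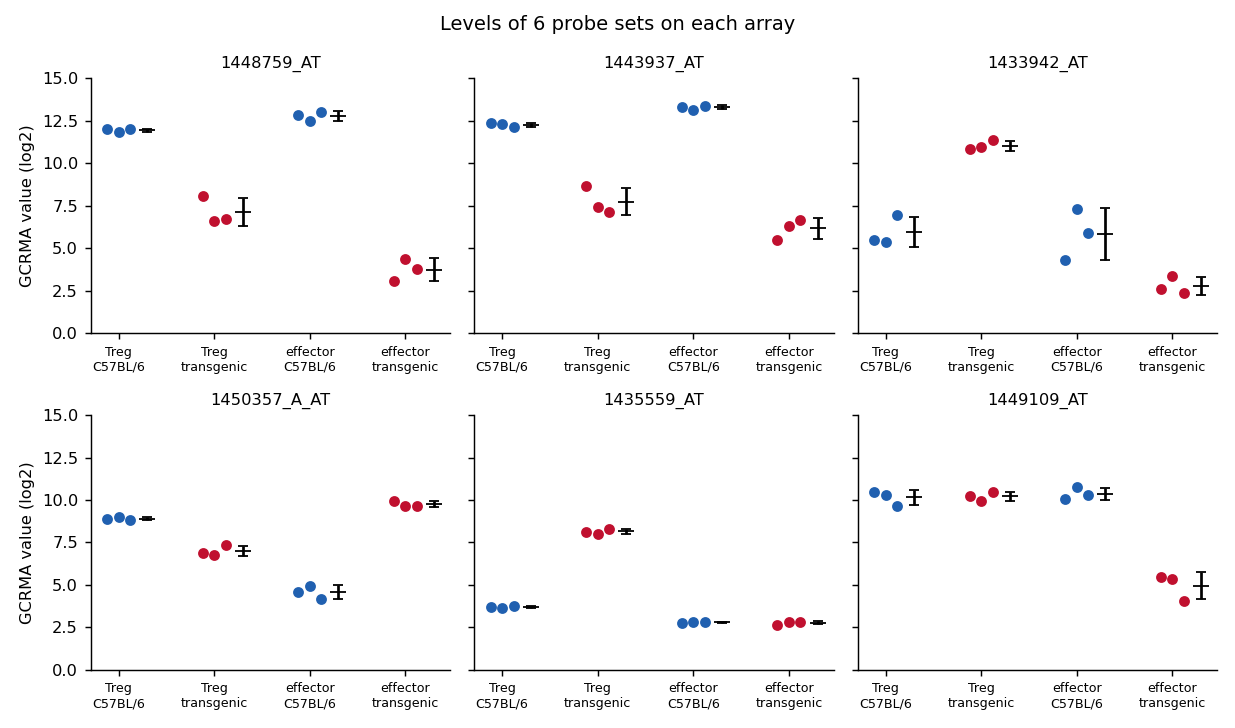
GCRMA values (log2 scale, vertical axis) of 6 probe sets on each of the 12 arrays, in C57BL/6 (blue) and transgenic (red) Treg and effector T cells, with the mean and SD of each group in black. Probe set 1448759_AT averaged 11.95 and 12.79 in C57BL/6 Treg and effector cells and 7.13 and 3.74 in transgenic ones, and 1450357_A_AT was lower in transgenic Treg cells and higher in transgenic effector cells.

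Both populations shared 33 called probe sets, against 6.53 if the lists were independent. Of these, 17 changed the same way, 9 falling and 8 rising, where independent lists would give 1.58 and 1.36. The other 16 changed in opposite ways, 12 of them lower in transgenic Treg cells and higher in transgenic effector cells (2.82 if independent) and 4 the other way (0.77 if independent). The largest shared falls were those of 1448759_AT and 1443937_AT, whose log2 changes were -4.82 and -4.53 in Treg cells and -9.06 and -7.14 in effector cells. The largest shared rise was that of 1449990_AT, by 3.32 in Treg cells and 3.45 in effector cells. No array served in both strain comparisons, but in the fit to all 12 arrays both use 1 residual variance per probe set, which makes probe sets of low variance easier to call in both, so the numbers for independent lists are not those of unrelated changes. With each population fitted alone, 8 were called in both (0.903 if independent), 5 of them in the same direction (0.417 if independent). Across all tested probe sets, which are not independent replicates, the strain changes of both populations correlated at 0.0023. The shared count was 10 without C57BL/6 Treg array 2, 11 without C57BL/6 effector array 2, transgenic Treg array 1 or transgenic Treg array 3, 11 without a filter, and 10 with the state of the arrays as a covariate. It was 123 with array weights and 48 with an intensity ratio of at least 2 and no test.

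**Figure D2:**
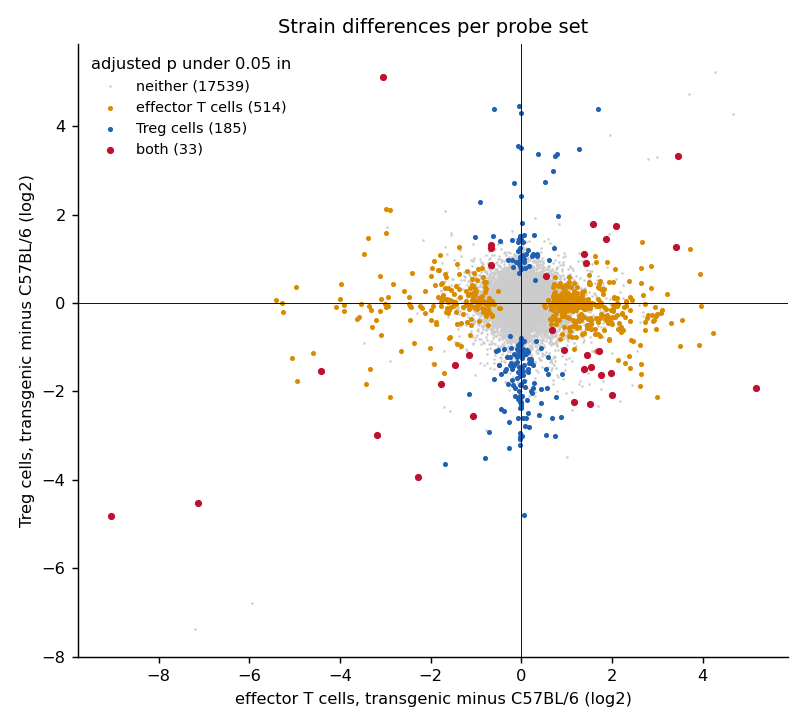
Log2 strain change (transgenic minus C57BL/6) in effector T cells (horizontal axis) and in Treg cells (vertical axis) for each of the 18271 tested probe sets, coloured by the comparison in which limma's adjusted p was under 0.05. Of these, 185 were called in Treg cells alone, 514 in effector cells alone and 33 in both.

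The strain difference itself differed between the populations in 413 probe sets, 277 with a lower and 136 with a higher strain change in Treg than in effector cells. With array weights the count was 2529, in nearly equal numbers (1262 lower, 1267 higher), and with an intensity ratio of at least 2 and no test it was 1756. Of the probe sets called in 1 population alone, 99 of 185 from Treg cells and 240 of 514 from effector cells passed this test, and the rest are not shown to differ between the populations. Probe set 1433942_AT had the largest positive difference (8.16 ± 0.92, log2 and standard error, limma adjusted p = 0.00109), since its log2 change was 5.10 in Treg and -3.06 in effector cells. Its transgenic effector arrays lay near the floor (2.38 to 3.36), so the size of this difference and its rank depend on the background correction. Probe set 1449109_AT fell by 5.41 on the log2 scale in effector cells and changed by 0.06 in Treg cells, a difference of 5.47 (limma adjusted p = 0.000502). Probe set 1450357_A_AT fell by 1.92 in Treg cells and rose by 5.18 in effector cells, a difference of -7.10 (limma adjusted p = 1.25e-06), and 1416111_AT had a difference of -5.11 (limma adjusted p = 0.00727). Both 1448759_AT and 1443937_AT fell further in effector than in Treg cells, with differences of 4.23 and 2.61 (limma adjusted p = 0.00262 and 0.0268). The sizes for 1448759_AT, 1449109_AT and 1450357_A_AT likewise depend on effector groups that averaged below a log2 value of 5. The count was 247 without C57BL/6 effector array 1 and also without transgenic Treg array 1, 251 without C57BL/6 effector array 2, 214 without C57BL/6 Treg array 2, and 261 without transgenic Treg array 3. It was 303 with the provider's run as a block in Treg cells.

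Treg and effector cells of C57BL/6 mice differed in 13475 probe sets, 5794 higher and 7681 lower in Treg cells. Transferrin receptor, the iron-uptake receptor that activated and dividing cells carry, was lower in Treg cells on each of its 3 control probe sets (limma adjusted p over the list alone of 1.76e-05 to 0.000531). Its 3′ probe set differed by -3.85 on the log2 scale, by -3.00 without C57BL/6 Treg array 1 and by -4.64 without C57BL/6 Treg array 3. Its other 2 averaged 7.33 and 7.93 in effector cells and 3.61 and 3.83 in Treg cells, below the level used for filtering. Gapdh, a glycolytic enzyme, was lower by 2.27-fold to 2.93-fold on its 3 probe sets, and beta-actin, of the cytoskeleton, was higher by 1.42-fold to 1.62-fold. Pyruvate carboxylase, which makes oxaloacetate from pyruvate, averaged 5.80 ± 0.11 in effector and 3.51 ± 0.11 in Treg cells on its 3′ probe set (log2, SD, n = 3), and its other 3 probe sets, at means of 2.31 to 3.69, lay below the level used for filtering in both populations. Probe sets 1456956_AT and 1423415_AT averaged 11.94 and 10.99 in Treg cells and 3.31 and 2.56 in effector cells, and 1450790_AT and 1449005_AT averaged 2.50 and 2.95 in Treg cells and 12.64 and 12.57 in effector cells. In each the lower group lay near the floor, as it did in 2583 of the 5794 higher and 1092 of the 7681 lower probe sets, where all 3 of its arrays were below a log2 value of 5, so the sizes depend on the background correction. The median difference of all tested probe sets was -0.26. After each array was centred on its median, 6940 probe sets were higher and 6230 lower, transferrin receptor differed by -3.41 to -3.79, Gapdh by -0.87 to -1.23 and beta-actin by 0.82 to 1.01. Population was confounded with culture, provider run and pooling of mice, which cannot be told apart from it here.

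The Treg-high set held 2712 probe sets and the Treg-low set 2379. Both sets come from fresh Treg against cultured, anti-CD3-activated effector cells. They therefore reflect culture, activation and provider run as well as cell type, which cannot be told apart here. In transgenic effector cells, 103 Treg-low probe sets fell and 23 rose, so that this set, 13.0% of those tested, gave 52.3% of all falls. Among Treg-high probe sets 101 rose and 3 fell in transgenic effector cells. Most of this set was below a log2 value of 5 on at least 1 C57BL/6 effector array, where values can hardly fall, and among the 570 of its probe sets above a log2 value of 5 on all 3 of those arrays 54 rose and 2 fell. The median strain change in effector cells was -0.21 for the Treg-low set, against -0.031 in simulations of unchanged strains that share the same C57BL/6 arrays, and 0.092 for the Treg-high set, against 0.025. Scored per array, the Treg-low set averaged 0.01 ± 0.02 on C57BL/6 and -0.20 ± 0.10 on transgenic effector arrays (SD, n = 3, exact permutation p = 0.1, two-sided, the smallest possible). The transgenic scores were -0.24 and -0.27 on arrays 2 and 3, in state 1, and -0.090 on array 1, in state 0 as were all 3 C57BL/6 effector arrays. With the state of the arrays as a covariate the medians were -0.12 for the Treg-low and 0.029 for the Treg-high set, so part of these shifts cannot be told apart from the state. The Treg-high scores were 0.00021 ± 0.022 and 0.029 ± 0.030 (SD, n = 3, exact permutation p = 0.4), and the median was 0.038 without transgenic effector array 3. Scores were taken from the mean of the C57BL/6 arrays, which also picked the sets. The strains are therefore not exchangeable, and the permutation p-values of the scores are not exact. The strain changes in effector cells had a covariance of 0.345 with the population differences across probe sets, against 0.047 in the simulations. Since the simulated noise was independent between probe sets, the simulated values do not bound what unchanged strains could give. The C57BL/6 arrays were too few to split, so part of the excess may come from sharing them. With the sets taken from the transgenic arrays, where sharing acts the other way, the medians were -0.090 for Treg-low and 0.011 for Treg-high probe sets.

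In transgenic Treg cells, 73 Treg-high probe sets fell and 20 rose, so 49.7% of all falls and 28.2% of all rises were in this set, which made up 14.8% of the tested probe sets. Probe sets near the floor can hardly fall, and among the 15696 above a log2 value of 5 on all 3 C57BL/6 Treg arrays the set made up 15.4% and held 52.5% of the falls. The set as a whole had a median strain change of -0.087, against -0.026 in simulations, and array scores of 0.0051 ± 0.21 for C57BL/6 and -0.076 ± 0.090 for transgenic mice (SD, n = 3, exact permutation p = 0.7, two-sided). The median was 0.00198 without C57BL/6 array 3 and 0.00910 with sets taken from the transgenic arrays, but -0.25 without C57BL/6 array 1 and -0.23 with the state of the arrays as a covariate, so neither its size nor its direction is settled. The sets share the C57BL/6 Treg arrays with the strain comparison, so part of the excess of falls may come from sharing them. For the same reason the permutation p of the Treg scores is not exact. The Treg-low set had a median of -0.010, 0.054 without C57BL/6 array 1 and 0.076 with the state of the arrays as a covariate. The covariance with the population differences was -0.086, against -0.046 in simulations. On the Treg-high set the C57BL/6 Treg arrays scored from -0.20 to 0.22, a shared deviation of whole arrays that the simulations leave out.

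None of the 13 probe sets of the named control genes passed the test between strains, adjusted over the list alone, in either population (0 at a limma adjusted p under 0.05). In Treg cells the 3′ probe set of the transferrin receptor averaged 6.09 ± 1.64 in C57BL/6 and 6.48 ± 0.43 in transgenic mice, and in effector cells 9.94 ± 0.66 and 9.32 ± 1.15 (log2, SD, n = 3). Bacterial and phage transcripts that are added before hybridization read 10.50, 11.63 and 12.65 on the C57BL/6 Treg arrays and 10.50 to 10.79 on the transgenic Treg arrays (exact permutation p = 0.4, two-sided, n = 3), and 9.98 to 10.42 on the effector arrays. The B2 repeat control probe set did separate the Treg strains, at 15.65 to 15.75 in C57BL/6 and 15.49 to 15.52 in transgenic mice (exact permutation p = 0.1, the smallest possible). Tested this way too were the spikes, 18S ribosomal RNA, transferrin receptor 3′, the B1 repeat and 3′ minus 5′ differences of beta-actin and Gapdh. None of these separated the strains in Treg cells, nor did any measure in effector cells. These p-values were not adjusted for the number of measures. The 3′ probe set of beta-actin did not overlap between Treg strains (15.87 to 16.01 in C57BL/6, 15.67 to 15.84 in transgenic mice). Nor did its M probe set (15.12 to 15.22, 14.90 to 15.09) or the 3′ one of pyruvate carboxylase (3.43 to 3.63, 3.67 to 3.96, below the filter level). The 3′ minus 5′ difference of beta-actin and the B1 repeat were lower on the transgenic array of each of the 3 Treg pairs, which were inferred from the data (exact permutation p = 0.3 and 0.5, two-sided, unpaired). The 18S ribosomal RNA probe sets ranged from 4.73 to 10.75 on the C57BL/6 Treg arrays.

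**Figure D3:**
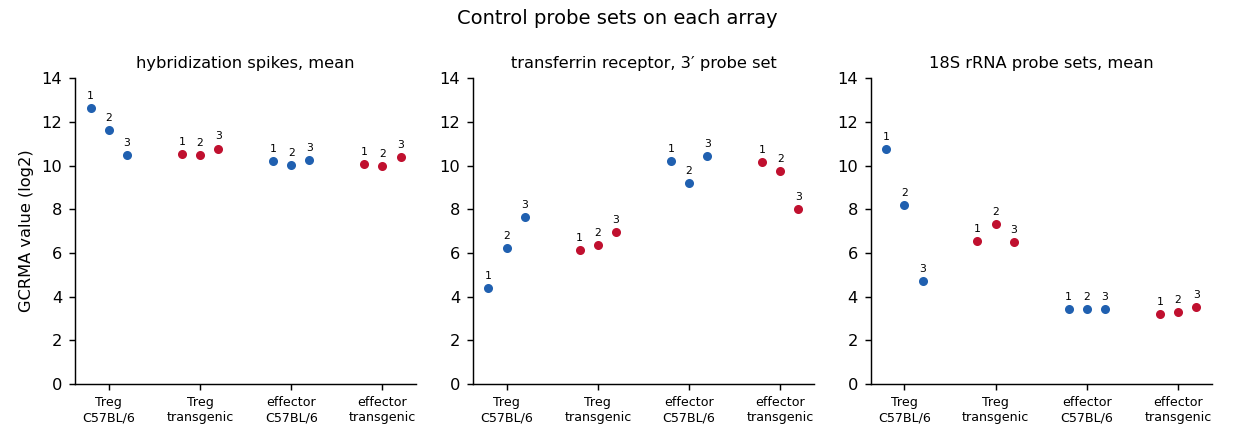
Mean log2 GCRMA value of the hybridization spikes, value of the transferrin receptor 3′ probe set and mean of the 18S ribosomal RNA probe sets on each array, by group, with replicate numbers beside the points. C57BL/6 Treg array 1 had the highest spike mean (12.65), the lowest transferrin receptor value (4.39) and the highest 18S value (10.75) of the 12 arrays.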

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

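The tests of other splits, of the spike reading as a covariate, of the states of the arrays, of the purification label and of the share of fresh Treg RNA were chosen after the results were seen. The position test of C57BL/6 Treg array 3 and the first test of a Treg share were set before.

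A difference between the populations was found in 413 probe sets, whose strain change differed between Treg and effector cells by limma's test of the difference. The differences of the named probe sets were 8.16 for 1433942_AT, 5.47 for 1449109_AT, -7.10 for 1450357_A_AT and -5.11 for 1416111_AT. Among 100 splits of the strains within each population, 1, the real one, gave as many as 413 probe sets. The highest other gave 199, in a draw that kept the real effector grouping and with it the effector strain changes. The real groupings with 1 population turned around were not drawn. These splits show that the count depends on the strain grouping, not that the strain changes differ between the populations. For the 17 probe sets that changed the same way in both populations, 1 of 100 splits, the real one, gave as many, and the highest other gave 0. Other splits of either population call few probe sets, so their shared counts lie near 0, and the real groupings with 1 population turned around, a split that was not drawn, would give the 16 opposite changes. The test therefore does not show that directions match.

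Treg cells of transgenic mice differed from C57BL/6 Treg cells in 218 probe sets, while the spike readings of C57BL/6 arrays 1 and 2 were the highest of all arrays. With the spike reading as a covariate, 162 of the 218 stayed past the threshold in the same direction, among 565 calls in that fit. Their median change was 1.05 times the original, a ratio over calls picked for staying. The slope rests largely on the C57BL/6 Treg arrays, which read 10.50 to 12.65, against 10.50 to 10.79 on the transgenic ones. That these 162 stayed argues against a linear trend with the readings as their whole cause. For the other 56 it stays open: their median fold went from 2.39 (quartiles 2.07 to 2.95) to 2.11 (1.80 to 2.62) and the standard error rose 1.24 times, which ended the call. Among 255 probe sets called without C57BL/6 array 3, that array lay at a median position of 0.742 between the transgenic mean at 0 and the other C57BL/6 arrays at 1. The 95% bootstrap interval, 0.657 to 0.821, is over probe sets, which are not independent replicates. The median lay between the bounds of 0.25 and 0.75 set before, with 22.0% of the probe sets under 0.25 and 49.8% above 0.75. Calling these probe sets on the other arrays can itself draw array 3 below 1, and being 1 array it decides nothing. With the 2 states of the arrays as a covariate 89 of the 218 stayed, with a median change 1.02 times the original, a ratio over calls picked for staying. The covariate is 1 state effect for both populations, estimated from C57BL/6 Treg and transgenic effector cells, the groups that hold both states. For the 89 this argues against such a common effect as their whole cause, but a state effect in 1 population alone is not removed. For the 129 that ended (median fold 2.39, then 2.30, standard error up 1.25 times) strain and state cannot be told apart. The defective IL-2 receptor, the age of the mice and the numbers pooled stay open, and 10 splits of the 6 arrays are too few for a share under 0.05: 1, the real one, gave 218, the highest other 4, and of the other splits that part all 3 pairs the highest 0.

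Activated effector cells of transgenic mice differed from C57BL/6 ones in 547 probe sets, and the purification label of transgenic array 3 describes fresh spleen cells. On a scale from C57BL/6 effector cells (0) to C57BL/6 Treg cells (1) that array lay at 0.045 over the Treg-high and Treg-low sets, which argues against fresh Treg cells on it. An added share of RNA like that of fresh Treg cells would have to reach 15.8% (lower quartile) to 34.1% (median) for the 101 called rises of Treg-high probe sets, yet 64 probe sets bright in Treg cells and near the floor in C57BL/6 effector cells rose by a median of 0.28, against 2.92 predicted from the lower share; the stricter test set before found only 1 probe set and is void, and Treg cells altered by the culture stay open. With the states of the arrays as a covariate 209 of the 547 stayed, with a median change 1.03 times the original, again over calls picked for staying. For the 209 this argues against a state effect common to both populations as their whole cause, but a state effect in 1 population alone is not removed. For the 338 that ended (median fold 2.13, quartiles 1.84 to 3.07, then 2.06, quartiles 1.75 to 2.80, standard error up 1.24 times) strain and state cannot be told apart. The defective receptor itself stays open as the biological explanation, and 10 splits of the 6 arrays are too few for a share under 0.05: 1, the real one, gave 547 and the highest other 9.

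For Treg against effector cells of C57BL/6 mice, 10 splits are likewise too few for a share under 0.05, with 13475 probe sets in the real split, the 1 with as many, and 0 in the highest other. Every other split mixes both populations on each side, so the population difference widens the residual spread and few calls could arise. Strain differences likewise widen the spread in the other splits of the strain comparisons, so their low counts are no measure of chance.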

How the results depend on the processing

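The array-weight, filter, normalization, threshold, block and leave-one-out alternatives were set before the data were examined; the spike covariate, the state covariate, the block in Treg arrays alone, and for the Treg-high and Treg-low sets the centring, the run block and the state covariate, were chosen after seeing the data. Not run, because probe sets were not paired with genes: the mean of a gene's probe sets, the fixed gene lists with their alternatives, and the fixed Treg list; testing all probe sets became the main analysis. The log2 changes of the 16 named values kept their direction and stayed past the threshold in all 400 alternative values (for the ratio without a test, a ratio of at least 2). They were picked as the largest called changes, so this does not extend to the other calls. Without a filter the counts were 347 (effector), 31870 (Treg against effector) and 11 (shared, same direction), with 45037 probe sets tested; a filter at log2 7 gave 135 (Treg). Array weights gave 1232 (Treg), 3033 (effector), 2529 (difference of strain changes) and 123 (shared), and the cause was not tested. The weights were estimated from the same arrays and were uneven. They ran from 0.24 to 5.02 on Treg arrays and from 0.23 to 3.93 on effector arrays. Fits to a contrast's own arrays gave 74, 223 and 5 (Treg, effector, shared), with fewer residual degrees of freedom. A ratio of mean intensities of at least 2 without a test gave 486, 908, 1756 and 48 (Treg, effector, difference, shared). The spike covariate gave 565 (Treg), and the state covariate 97, 220 and 10 (Treg, effector, shared). Leaving out 1 array at a time gave 135 to 255 (Treg), 266 to 628 (effector), 12519 to 13909 (Treg against effector), 214 to 433 (difference) and 10 to 19 (shared), with fewer samples; of the 218 Treg calls 127 to 198 were kept, and of the 547 effector calls 259 to 533.

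With the replicate number as a block the counts were 184 (Treg), 522 (effector), 13380 (Treg against effector), 371 (difference) and 14 (shared). With the block in the paired Treg arrays alone they were 354 (Treg), 503 (difference) and 20 (shared). Those pairs were inferred from these same arrays, which can itself raise the counts. Among named probe sets the block changed no call. Same-numbered effector arrays correlated at 0.21, -0.34 and -0.34, and not every effector array correlated best with its own number, nor did every Treg array.

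The strain change of the Treg-low set in Treg cells turned to 0.046 with 2-fold sets, 0.00673 after quantile normalization and 0.00540 with a filter at log2 7, and was -0.0812 with sets from transgenic arrays; that of the Treg-high set turned to 0.00910 with sets from transgenic arrays. In effector cells the Treg-high set had 0.011 and the Treg-low set -0.090 with sets from transgenic arrays, which share arrays the other way, and the Treg-high set 0.24 with a filter at log2 7; the cause of the others was not tested. With the state covariate the Treg-low set had 0.076 in Treg cells (turned) and -0.12 in effector cells, and the Treg-high set -0.23 and 0.029. Centring gave -0.10 (Treg-high) and -0.047 (Treg-low) in Treg cells, and 0.079 and -0.24 in effector cells. Leaving out 1 array gave -0.25 to 0.00198 (Treg-high) and -0.022 to 0.054 (Treg-low) in Treg cells, and 0.038 to 0.11 and -0.28 to -0.17 in effector cells; the run block gave -0.045 and -0.017 in Treg cells. Of 904 other values, 849 stayed on their side of the threshold or within 1.5 times, 48 counts of higher or lower probe sets moved further (17 up, 31 down), 7 beta-actin values no longer passed (6 under a 2-fold minimum, and the 5′ probe set without C57BL/6 effector array 2) and 0 turned direction. Changes near the GCRMA floor limit what folds can show.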

Other observations

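The tests in this part were chosen after the result was seen.

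In 12 tested probe sets the largest gap between neighbouring arrays exceeded 2 on the log2 scale and separated arrays of both populations. Of these, 9 made the same split of the 12 arrays, with gaps of 2.00 to 10.5, and 2 made the split by strain. The 6 arrays of one state were the 3 C57BL/6 effector arrays, transgenic effector array 1 and C57BL/6 Treg arrays 1 and 2, and the other 6 arrays were in the other state. In that first state 2 of the 9 probe sets were high and 7 low. These 9 probe sets were called in neither strain comparison (0 in each), since the split crosses the groups. The labels do not give the sex of the mice, and with no gene names used here it was not tested whether these probe sets lie on the sex chromosomes. With 5 of 6 C57BL/6 arrays in one state and 5 of 6 transgenic arrays in the other, the state is nearly confounded with strain. With it as a covariate, 89 of 218 calls in Treg cells and 209 of 547 in effector cells stayed past the threshold. The folds of the lost calls stayed about as large (medians 2.39, then 2.30, in Treg cells and 2.13, then 2.06, in effector cells) while their standard errors rose 1.25 and 1.24 times. Near confounding widens the errors whatever the cause, so for the lost calls strain and state cannot be told apart.

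Across the 6 Treg arrays the mean spike reading correlated with the 18S ribosomal RNA value at r = 0.907 (exact permutation p = 0.0153, adjusted over 4 relations 0.0389) and rho = 0.771 (exact permutation p = 0.103, adjusted 0.181). Without the 2 arrays farthest from the median reading, r was 0.180, so the relation rests on those arrays. For the transferrin receptor 3′ probe set r was -0.827 (exact permutation p = 0.0597, adjusted 0.0597) and rho -0.714 (exact permutation p = 0.136, adjusted 0.181), and r was 0.128 without those 2 arrays. The other 2 relations, with the 3′ minus 5′ differences of beta-actin and Gapdh, had r = 0.854 and 0.850 (exact permutation p = 0.0292 and 0.0264, adjusted 0.0389 each) and rho = 0.600 and 0.829 (exact permutation p = 0.242 and 0.0583, adjusted 0.242 and 0.181), and r was -0.732 and -0.304 without those 2 arrays.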
